A study of Caenorhabditis elegans with 4 samples.

How the data were processed

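Whole larvae of 2 genotypes, wild type and dve-1 mutant, were profiled by RNA-seq with 2 libraries each, and groups and replicate numbers were taken from the sample names. The deposited table holds 1 value per RefSeq transcript accession and library in 52491 rows, with a header that names no unit. The values were read as FPKM as the authors deposited them: they are not whole numbers, their sums per library exceed what TPM would give, and the submitters' processing notes name TopHat2, Cufflinks and the ce11 genome, without versions or settings. Whether Cufflinks also scaled the libraries to each other, the library kit and its strandedness are not given in the sources used here. FPKM are not counts, so no count model was used. Per the labels, RNA was total RNA.

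Accessions were matched to genes through the RefSeq annotation of WBcel235, which has the same coordinates as ce11, ignoring version numbers. Of 52491 accessions, 47645 (90.8%) matched, 26542 of them with the same version, and 4846 did not. Matched accessions held 76.8% to 78.4% of the summed FPKM of a library. FPKM were summed per gene over matched accessions, giving 41614 genes, 17970 of them protein-coding, and a gene with an unmatched isoform is therefore understated. Of these genes, 47 were listed at 0 in some library with a median above 50 FPKM, so an exact 0 can be a failed estimate and is described only as listed at 0, with no fold against such a group. Transcript lengths came from Ensembl release 115. No column of other samples was present.

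Depth was estimated from 1509 protein-coding genes with a single transcript: FPKM times length falls in steps of 1 fragment, and 69.6% to 72.0% of low values lay within 0.1 of a whole number of fragments at the best step. This assumes values scaled to the number of mapped fragments and to nothing else. The steps correspond to about 14100000 to 15300000 fragments per library.

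Tests used limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(FPKM + 1), for genes with at least 1 FPKM in at least 2 libraries. Benjamini-Hochberg adjusted p under 0.05 was the threshold, two-sided. Fold changes are dve-1 mutant minus wild type on the log2(FPKM + 1) scale, which understates changes of low genes. The moderated test had 3.84 degrees of freedom, and the median standard error was 0.26 on the log2 scale. Lists were tested with camera, two-sided, with a preset inter-gene correlation of 0.01, adjusted over the 41 of 43 lists with at least 5 tested members, and again with an estimated correlation and with fry. The yolk list had 4 tested members. The list of genes on the mitochondrial genome matched none, because the annotation gives those genes other names (such as ND3 and COX1), so they were tested as single genes and not as a list. Python 3.11.15 with pandas 2.3.3 prepared the tables.

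The tests, the lists, the alternatives and the genes to name were fixed before the data were examined, except where a choice is said to have been made after. Named genes were 19 chosen in advance for the question, up to 12 per direction with the largest log2 fold change among those past the threshold with a mean of at least 5 FPKM and groups that did not overlap, and up to 4 members per list with the smallest p. The text gives those that matter most. The alternatives were limma without the trend, median-centring, quantile normalization, other filters, a pseudocount of 0.1, a replicate block, each library left out, other thresholds, and leaving out the sperm, collagen and molting-cycle lists. After the data were seen, restriction to protein-coding genes, to protein-coding genes with at least 1 FPKM and at least 20 estimated fragments in all 4 libraries, single accessions, and a crossed pairing were added. Several similar filters on gene class and fragments were looked at before these were kept.

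The limma and camera steps were tested on simulated data, with values drawn around the means of the 14664 tested genes with their estimated spread and 200 genes changed by known folds. In that run 8 of 14464 unchanged genes were called, and in a run with no changed gene 0 were called. Noise was drawn independently for each gene and library, and only genes of middle level were changed. These rates therefore do not cover differences that libraries share. Correlations of log2(FPKM + 1) across genes, which are not independent replicates, were 0.926 between the wild type libraries and 0.912 between the mutant libraries, and 0.908 to 0.930 between genotypes, with no pair of identical libraries.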

Results

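RNA-seq measured transcript levels in whole larvae of the nematode Caenorhabditis elegans, comparing wild type animals with animals that carry the dve-1 allele uf171. DVE-1 is a homeodomain protein known from the mitochondrial unfolded protein response. Each genotype had 2 libraries, 4 in all. The sample names and the stage label give L4, the last larval stage, whereas the protocol text speaks of collected L1 larvae, so the stage is given here as labelled. Values were FPKM, fragments scaled to transcript length and to the mapped fragments of the library. The depth behind them, estimated from the steps between low values, was about 14900000 and 15300000 fragments in wild type replicates 1 and 2, and about 14300000 and 14100000 in dve-1 mutant replicates 1 and 2. At least 1 FPKM was reached by 14537 and 14339 genes in the wild type libraries and by 14318 and 14411 genes in the mutant libraries. Nothing in the labels says whether the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

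The targeted gene itself was measured first. dve-1 (ZK1193.5; chromosome X, 427035 to 433812 on the minus strand, WBcel235) stood at 14.19 and 13.87 FPKM in the wild type libraries and at 22.98 and 21.13 FPKM in the dve-1 mutant libraries. The means were 14.03 ± 0.228 (SD, n = 2) and 22.1 ± 1.31 FPKM (SD, n = 2), a ratio of 1.57. Its log2 fold change of 0.62 (SE 0.18, 95% interval 0.11 to 1.12, limma) did not pass the adjustment over all genes, with an adjusted p of 0.874. The labels do not describe uf171 as a deletion, and FPKM values cannot show the allele, so this level does not check the genotype labels.

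The same comparison asked which genes differed between the genotypes. Of 14664 genes tested, 19 passed, with 10 higher and 9 lower in the dve-1 mutant, and 18 of these were short non-coding RNAs, the shortest spanning 54 nucleotides. Each of the 18 was listed at 0 in both libraries of 1 genotype. The microRNA gene mir-80 was at 32.2 and 31.2 FPKM in wild type and listed at 0 in both mutant libraries, and mir-261 was at 30.8 and 29.8 FPKM in wild type and listed at 0 in the mutant (limma adjusted p = 0.0347 for both). T23B12.14 had 827 and 802 FPKM in wild type, T26H2.15 had 2159 and 4186 FPKM, and both were listed at 0 in the mutant (adjusted p = 0.0109 and 0.0233). In the other direction, C14A11.14 and F13G3.13 were listed at 0 in wild type and each read 243 and 247 FPKM in the mutant libraries (adjusted p = 0.0121). The spliced leader RNA genes sls-1.1 and sls-1.5, which are near-identical copies of each other, both read 20.2 and 20.6 FPKM in the mutant and were listed at 0 in wild type (adjusted p = 0.0406). FPKM of RNAs this short can rest on very few fragments.

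The other gene that passed was oac-59, a predicted acyltransferase (C42C1.7; chromosome IV, 12293233 to 12301261 on the minus strand). It stood at 2.26 and 2.31 FPKM in wild type and at 63.3 and 65.3 FPKM in the mutant, with means of 2.29 ± 0.0289 and 64.3 ± 1.44 FPKM (SD, n = 2). The log2 fold change was 4.31 (SE 0.18, limma adjusted p = 0.0347). The difference sat on 1 of its 2 transcript accessions, which was listed at 0 in both wild type libraries and read 60.47 and 62.01 FPKM in the mutant. The other accession stood at 2.26 and 2.31 FPKM in wild type and at 2.84 and 3.34 FPKM in the mutant. The annotation holds 2 oac-59 transcripts, of 2226 nucleotides in 11 exons and of 162 nucleotides in 1 exon, the latter at 12293358 to 12293519.

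Among protein-coding genes tested on their own, a choice made after the data were seen, limma called 0 of 13479, with 545 at an unadjusted p under 0.05. Over all genes, 674 lay under that unadjusted p where chance gives 733. Simulated data of the same size and spread, with noise independent between genes and libraries, were used to see what this design can find. Of 50 genes of middle level changed by a log2 fold of 1, 1 was called. At log2 folds of 2, 3 and 4, 25 of 50, 41 of 50 and 48 of 50 were called. The real libraries also share differences that cross the genotypes, with 58 genes called in 1 such split. These rates may therefore not hold for the real data. Leaving out any 1 library ended all 19 calls, as did the replicate block, each a fit with 1 residual degree of freedom in place of 2. The log2 fold changes themselves stayed at 0.959 to 1.04 times their size in these fits, for oac-59 at 4.29 to 4.34 and for mir-80 at -5.05 to -5.01. This was largely fixed in advance, because calling favours replicates that agree and the replicate block cannot move a fold change. It is therefore no evidence that the changes are real.

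The genes named in advance for the mitochondrial stress response, GABA signalling and the neuromuscular synapse had no member past the threshold. hsp-60, a mitochondrial chaperonin, stood at 404 and 282 FPKM in wild type and 458 and 476 FPKM in the mutant (log2 fold change 0.47, 95% interval -0.15 to 1.09), and the log2 fold change was 0.73 without wild type replicate 1 and 0.21 without wild type replicate 2. atfs-1, the transcription factor that drives the mitochondrial unfolded protein response, stood at 86.3 and 80.3 against 101 and 96.3 FPKM (log2 fold change 0.24, 95% interval -0.15 to 0.64). For clpp-1 and ubl-5 the log2 fold changes were -0.08 and 0.08, for lin-65 0.26 and for met-2 0.15, and those of ubl-5, lin-65 and met-2 changed sign when 1 library was left out. unc-25, the GABA-synthesising enzyme, read 46.2 and 46.1 FPKM in wild type and 37.4 and 34.8 FPKM in the mutant (log2 fold change -0.35, 95% interval -0.78 to 0.09). unc-47 and unc-30, the vesicular GABA transporter and a homeodomain regulator of GABA neurons, had log2 fold changes of 0.10 and 0.17. The GABA receptor gene unc-49 read 49.7, 42.3, 11.3 and 48.3 FPKM in wild type replicates 1 and 2 and mutant replicates 1 and 2, so its log2 fold change of -0.93 came from mutant replicate 1 and was 0.07 without it. The acetylcholine receptor subunits acr-12, unc-29, unc-38 and unc-63 had log2 fold changes of 0.31, -0.35, -0.13 and 0.05, of which the last pair changed sign when 1 library was left out, and the receptor-clustering gene lev-10 had 0.17. For the ubiquitin genes ubq-2 and uba-1 the values were -0.11 and 0.21. Apart from dve-1, every one of these genes had a limma adjusted p of 0.9995. hsp-6 was not analysed here.

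**Figure D1:**
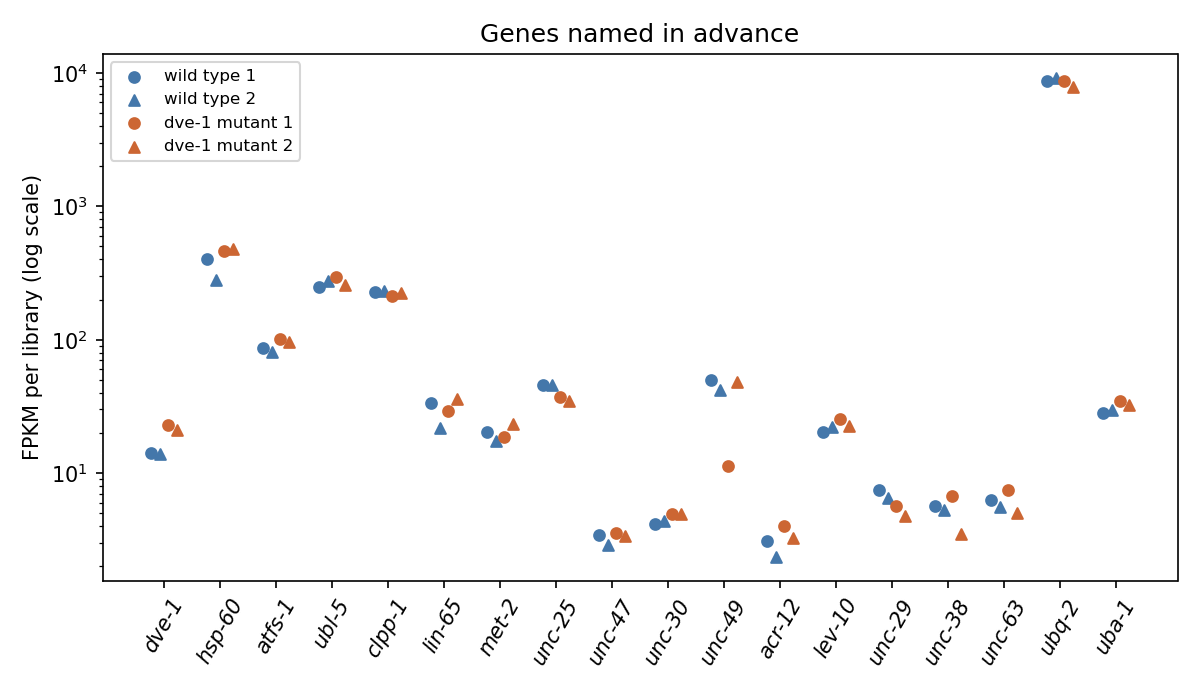
FPKM of the 18 measured genes named in advance, on a log axis, with 1 point per library: blue for wild type, orange for the dve-1 mutant, circles for replicate 1 and triangles for replicate 2. The dve-1 points of the mutant, at 22.98 and 21.13 FPKM, lie above those of wild type, at 14.19 and 13.87 FPKM, and none of these genes passed the adjusted test.

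Gene lists fixed before the data were examined were then compared as groups with camera. Histone genes lay lower in the dve-1 mutant: of 67 tested, 59 were lower and 8 higher by sign, with a median log2 fold change of -0.35 (adjusted p = 4.6e-09 with the preset correlation, adjusted p = 0.878 with an estimated correlation). his-6 stood at 12.4 and 13.5 FPKM in wild type and at 6.82 and 7.17 FPKM in the mutant, and his-18 at 18.02 and 19.97 against 12.7 and 10.84 FPKM. No histone gene passed on its own, and 0 passed when adjusted over the list alone. The median of the list was highest in wild type replicate 2 and lowest in mutant replicate 2, at 13.8 and 8.07 FPKM, with 12.5 FPKM in wild type replicate 1 and 10.8 FPKM in mutant replicate 1. Histone genes are near-identical copies, so the division of fragments among them is uncertain, and his-28 and his-50 carried the same values in every library. The test counted such copies as separate genes, so the adjusted p with the preset correlation may be too small.

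Markers of the intestine lay higher, with 24 of 26 tested members higher by sign and a median log2 fold change of 0.22 (adjusted p = 2.4e-04 with the preset correlation, adjusted p = 0.878 with an estimated correlation). act-5, an intestinal actin, read 774 and 782 FPKM in wild type and 1310 and 937 FPKM in the mutant, and the cysteine protease gene cpr-1 read 285 and 398 against 566 and 443 FPKM. The list median did not separate by genotype, at 79.1 and 101 FPKM in wild type and 125 and 98.7 FPKM in mutant replicates 1 and 2. Groups that did not overlap were found for 10 of the 26 members, all 10 higher in the mutant. Over both directions chance gives 33.3%, and all tested genes gave 28.1%. Its median log2 fold change was 0.09 without wild type replicate 1 (adjusted p = 0.452) and 0.12 without mutant replicate 1 (adjusted p = 0.229), against 0.46 without wild type replicate 2 and 0.39 without mutant replicate 2. Over the alternatives tested with camera, the adjusted p ran from 7.5e-08 to 0.878. Molting-cycle genes lay lower, 26 of 33 by sign, with a median of -0.33 (adjusted p = 0.0495, adjusted p = 0.878 with an estimated correlation). In that list the hedgehog-related gene wrt-2 read 182.2 and 191.3 against 120 and 84.6 FPKM and nas-37, a protease of the molt, 78.6 and 74.4 against 53.6 and 39.4 FPKM, while mlt-7, a peroxidase, read 14.8 and 13.5 against 32.2 and 31.5 FPKM. The molting call was lost while the median stayed near its size with median-centred values (-0.32, adjusted p = 0.0522), with the replicate block (-0.33, adjusted p = 0.0833), without wild type replicate 1 (-0.28, adjusted p = 0.055) and without wild type replicate 2 (-0.30, adjusted p = 0.202). Without mutant replicate 2 the median was -0.20 (adjusted p = 0.778), and the adjusted p lay in a range of 0.00621 to 0.878 over the alternatives tested with camera.

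The lists of sperm, oocyte, cell cycle and collagen genes passed the preset test, and the median of each turned when 1 mutant library was left out. In those fits the sperm and oocyte lists passed the preset test in the opposite direction, while the cell cycle and collagen lists did not pass. For sperm and oocyte the direction called thus depended on which mutant library was kept. Sperm genes, among them the major sperm proteins, were lower by sign for 83 of 90 members (median -0.36, adjusted p = 0.00105, adjusted p = 0.878 with an estimated correlation). Their median was 80.2 FPKM in mutant replicate 1 and 194 FPKM in mutant replicate 2, against 188 and 142 FPKM in wild type, and without mutant replicate 1 the median log2 fold change was 0.26. The sperm call was also lost without wild type replicate 1, where the median was -0.14 (adjusted p = 0.189). Oocyte genes were higher by sign for 22 of 23 members (median 0.42, adjusted p = 0.0252, adjusted p = 0.878 with an estimated correlation). Their median was 17.9 FPKM in mutant replicate 1 and 59.7 FPKM in mutant replicate 2, against 29.2 and 18.9 FPKM in wild type, and without mutant replicate 2 the log2 fold change turned to -0.36. The oocyte call was also lost without wild type replicate 1 or 2, where the median was 0.64 and 0.15 (adjusted p = 0.055 and 0.231). Cuticle collagens were higher by sign for 82 of 127 members (median 0.32, adjusted p = 0.0204, adjusted p = 0.878 with an estimated correlation), with a median of 330 FPKM in mutant replicate 2 and of 106, 114 and 128 FPKM in wild type replicates 1 and 2 and mutant replicate 1. Without mutant replicate 2 the median log2 fold change of the collagens was -0.43. Their call was also lost without wild type replicate 1, where the median was 0.35 (adjusted p = 0.401), and with no filter on low values, where the median was 0.14 (adjusted p = 0.0503). Within the collagen list, col-125 read 1375 and 1685 against 2900 and 2664 FPKM and col-156 read 28.8 and 46.9 against 128 and 221 FPKM, whereas col-110 read 327 and 282 against 152 and 175 FPKM and bli-2 read 1629 and 1324 against 818 and 832 FPKM. Cell cycle genes were higher by sign for 29 of 34 members (median 0.13, adjusted p = 0.0495, adjusted p = 0.878 with an estimated correlation), and their median turned to -0.09 without mutant replicate 2 (adjusted p = 0.741). Without wild type replicate 2 it was -0.03 (adjusted p = 0.573), and with the replicate block, which left the median at 0.13, the call was lost (adjusted p = 0.0833).

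**Figure D2:**
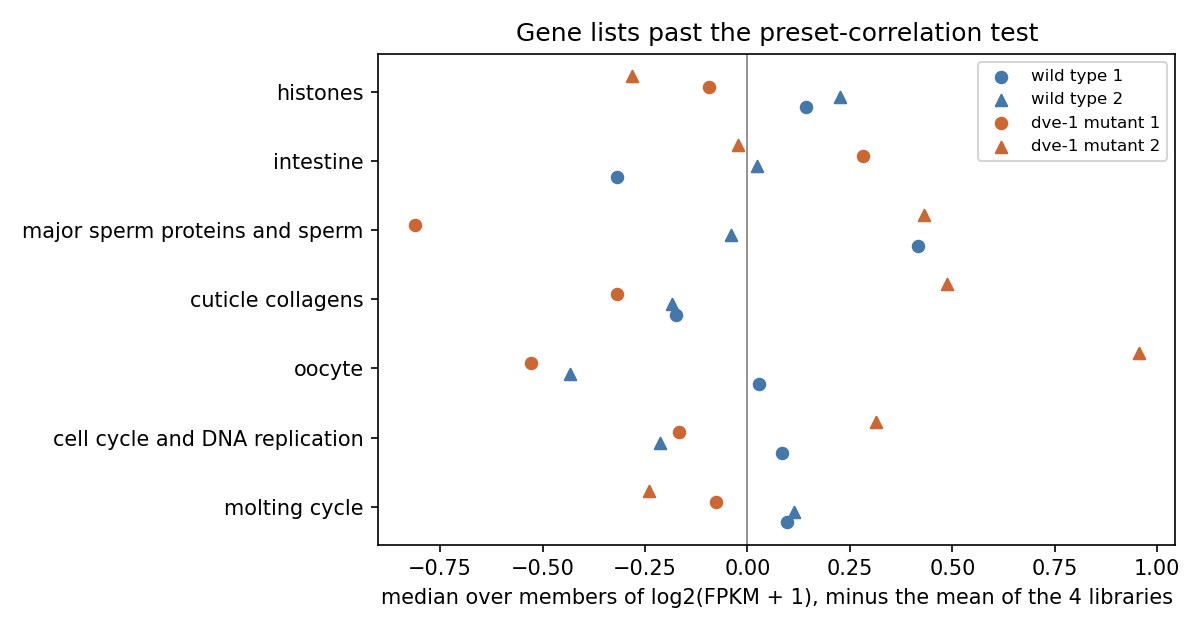
Position of each library in the 7 gene lists past the preset-correlation test: the horizontal axis is the median over members of log2(FPKM + 1) after subtracting each gene's mean over the 4 libraries, and each point is 1 library (blue wild type, orange dve-1 mutant, circles replicate 1, triangles replicate 2). Histone and molting-cycle points separate by genotype, while in the sperm and oocyte lists the mutant replicates lie farther apart than the genotypes, at -0.81 and 0.43 for sperm.

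The lists closest to the question did not pass. Of the mitochondrial unfolded protein response, 17 of 23 members were higher by sign with a median log2 fold change of 0.08 (adjusted p = 0.189), and 0 passed alone or when adjusted over the list alone. GABAergic genes had 17 of 24 members lower by sign and a median of -0.07 (adjusted p = 0.502). In that list ttr-39 had the smallest unadjusted p, with 30.8 and 28.3 FPKM in wild type and 20.7 and 19.7 FPKM in the mutant. Cholinergic synapse genes had a median of 0.03 (adjusted p = 0.595) and presynaptic genes of -0.01 (adjusted p = 0.502), where slo-1, a calcium-activated potassium channel, read 17.7 and 17.4 against 10.4 and 8.10 FPKM. Proteasome subunits were lower by sign for 30 of 31 members, by a median of -0.10 (adjusted p = 0.178), cytosolic ribosomal proteins for 55 of 58, with a median of -0.09 (adjusted p = 0.113), and mitochondrial ribosomal proteins were higher for 45 of 65, with a median of 0.06 (adjusted p = 0.103). Ubiquitin conjugation genes had a median of -0.03 over 220 members (adjusted p = 0.534). Neuropeptide genes were lower by sign for 89 of 117 members, with a median of -0.11 (adjusted p = 0.0517). The insulin-like gene ins-13 ran against its list, at 4.01 and 3.89 FPKM in wild type and 13.9 and 14.1 FPKM in the mutant (log2 fold change 1.60, limma adjusted p = 0.180). Homeobox genes, dve-1 among them, had a median of -0.09 over 70 members (adjusted p = 0.558).

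Across the 41 lists, 7 passed with the preset correlation, 4 higher and 3 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.878. Adjusted over the list alone, 1 gene passed in the 41 lists, the germline gene pgl-1, which was listed at 0 in both wild type libraries and read 10.4 and 11.9 FPKM in the mutant (adjusted p over all genes = 0.0575). It rests on 1 of its 2 annotated accessions.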

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

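The tests of explanations in this part were chosen after the results they bear on were seen. A transcript accession that matched no gene, and so entered no comparison by gene, was listed at 0 in both wild type libraries and read 429 and 371 FPKM in the dve-1 mutant libraries, a mutant mean of 399.7 FPKM (limma adjusted p = 0.0166 over 20088 accessions). It was singled out because it passed the threshold among single accessions in data that the comparison by gene did not use. Its 0 in wild type played no part in that choice, and an exact 0 can be a failed estimate.

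The 18 called short RNAs, such as mir-80, T23B12.14 and sls-1.1, were each listed at 0 in both libraries of 1 genotype. C14A11.14 and F13G3.13, both spanning 68 nucleotides, carried the same values in every library. The same held for sls-1.1 and sls-1.5, also of 68 nucleotides. Each was counted as a separate gene, so the 18 calls may not be independent. For 15 of the 18, the ratio between the 2 replicates above 0 equalled the ratio of what 1 fragment is worth in those libraries, times a ratio of whole numbers up to 3, within 0.5%. Calling favours replicates that agree, so RNAs that were not called were counted as well. Of those no longer than the 18 and listed at 0 in both libraries of 1 genotype, 26 of 40 did so. Of all uncalled non-coding RNAs of that length, 121 of 382 ratios (31.7%) did. For deep protein-coding genes it was 10.3% of ratios where replicates agree within 5%, and 2.63% of all ratios. A candidate explanation is that most of these values rest on the same few fragments in each replicate, which would make the spread look smaller than counting allows. A genotype effect stays open: the other 2 splits of the 4 libraries called 47 and 9 non-coding RNAs listed at 0 on a side, 26 and 8 of them no longer than the 18 of the labelled split. Called or not, non-coding RNAs listed at 0 on a side numbered 154 in the labelled split and 169 and 135 in the other 2. Such RNAs were thus about as common in splits that ignore genotype.

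oac-59 passed because 1 accession, listed at 0 in wild type, held 95.2% of its FPKM in the mutant. The log2 fold change of the gene was 4.31, with an interval that began at 3.80. The other accession did not show an increase of that size, at 0.31 (95% interval -0.46 to 1.09). A smaller increase of the whole locus lies within that interval and stays open. The value of the gene is a sum held mostly by the accession listed at 0 in wild type, so the comparison is not independent. It also cannot decide the question if fragments were divided wrongly between the accessions. Whether the accession listed at 0 in wild type is the annotated 162-nucleotide isoform, which lies within the span of the longer one, was not checked. If so, assignment of fragments to that isoform and a real change of it cannot be told apart. Values per accession do not show where the fragments lie.

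Libraries of the same genotype lay far apart: the split of wild type 1 and mutant 2 against wild type 2 and mutant 1 called 58 genes with 2380 at an unadjusted p under 0.05, against 19 and 674 for the labelled split and 9 and 290 for the remaining split. With 3 splits in all, their number is too small for a share under 0.05, but a split with several times the calls points to a structure of the samples that crosses the labels. Sequencing depth is argued against, since 17.6% of 3373 protein-coding genes with at least 1000 estimated fragments passed that unadjusted p in the same split. Developmental stage at collection may contribute, as 3 of the 4 tested stage lists named in the design were among the 8 of 41 lists with the largest mean difference between replicates, but of these only oocyte and sperm differed in both genotypes (0.46 in wild type for each, 1.48 and 1.24 in the mutant), while collagens differed by 0.81 in the mutant and 0.0097 in wild type and the molting cycle was not among the 8. A swapped label cannot be told apart from the labelled grouping by dve-1, which separated by label (log2 fold change 0.62), because FPKM values do not show the allele.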

How the results depend on the processing

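Protein-coding filters, single accessions and the crossed pairing were chosen after the data were seen. The 19 gene calls became 86 without the trend, 3 with no filter, 10 with at least 5 FPKM, 10 with a pseudocount of 0.1, 82 at an adjusted p under 0.1 and 0 at 0.01, and 10 of 20088 for single accessions. All 10 of the calls at 5 FPKM, all 10 at the lower pseudocount and the 3 with no filter were among the 19. The 1 protein-coding call became 7 without the trend (oac-59 with pgl-1, gpi-1, pfkb-1.1, mps-4, C32E8.12 and Y46C8AL.11), 0 with no filter, 8 at an adjusted p under 0.1 and 2 with the sperm, collagen and molting-cycle lists left out. limma called 0 protein-coding genes when they were tested alone (545 at an unadjusted p under 0.05) and 0 of 11813 with at least 20 estimated fragments (434 at that p). Each of the 4 fits that left out a library called 0 (range 0 to 0), with 514 to 859 genes at an unadjusted p under 0.05; there the lone library was assumed to vary like the other group. The replicate block called 0 (517 at an unadjusted p under 0.05) and the crossed pairing 0 (1265 at that p). Deviations of same-numbered libraries from their group mean correlated at -0.19 across genes. With 2 libraries per group the value for crossed numbers, 0.19, is the same result with its sign turned. The libraries share only a number. Median-centring gave 14 calls, quantile normalization 19 and leaving out the sperm, collagen and molting-cycle lists 27. The cause of these shifts was not tested, apart from the fewer libraries or genes in some fits.

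The count of 7 lists became 0 with an estimated correlation and 0 with the directional test of fry, 11 with at least 20 estimated fragments, 5 with the replicate block and 4 to 9 with a library left out. The fry test for change in either direction passed for 2 lists, neuropeptides (adjusted p = 0.00355) and germline proliferation and meiosis (adjusted p = 0.00375). In the germline list pgl-1, listed at 0 in both wild type libraries, had an unadjusted limma p of 1.3e-04. The next smallest was 0.0836, for fog-1. Whether that list result rests on pgl-1 alone was not tested. Of single lists, sperm turned to 0.26 without dve-1 mutant replicate 1, and oocyte, cell cycle and collagens to -0.356, -0.0944 and -0.434 without dve-1 mutant replicate 2, and the cause was not tested. With a library left out their medians ranged from -0.94 to 0.26 for sperm, -0.36 to 1.19 for oocyte, -0.0944 to 0.38 for cell cycle and DNA replication, and -0.43 to 0.58 for collagens. Histones kept their direction and stayed past the threshold in every refit with the preset correlation. Their median could not have turned with a library left out, as 43 of 67 members were lower with groups that did not overlap. dve-1 kept its direction and its side of the threshold in every alternative, with log2 fold changes of 0.56 to 0.67. Over all alternatives, named genes gave 2513 values on the same side and direction, 155 no longer past the threshold, 1 newly past it and 13 with a changed sign where no test had passed. The 155 can come only from the called genes. Most named genes were not called, and for them the same side means only that they stayed uncalled. Some alternatives, such as the replicate block, also cannot move a fold change. The 2513 values therefore do not measure how stable the calls were. Depth limits the short RNAs, whose values can rest on a few fragments.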

Other observations

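Families of protein-coding genes that share a name were scanned with camera after the data were seen, 339 families with at least 5 tested members. With the preset correlation 9 passed, 5 higher and 4 lower in the dve-1 mutant, and 0 passed with an estimated correlation (adjusted p = 0.998 with an estimated correlation for each of those named here). The nspb family, small nematode-specific peptides, was higher for 12 of 12 members, with a median log2 fold change of 2.12 (adjusted p = 1.7e-11 with the preset correlation). Its median was 6.47 and 16.3 FPKM in wild type and 66.3 and 47.4 FPKM in the mutant, and all 12 had groups that did not overlap, where chance gives 33.3% and all tested genes gave 28.1%. The test counted the 12 as separate genes, but the division of fragments between similar copies is not known here, and nspb-2 and nspb-3 carried the same values in wild type replicate 2 and in mutant replicate 2. The abu family, named for activation in blocked unfolded protein response and known from the pharyngeal cuticle, was higher for 9 of 10 members with a median of 1.87 (adjusted p = 2.0e-07), at 13.96 and 27.98 against 68.9 and 111.1 FPKM. The idpc family was higher for 7 of 7 members (median 1.296, adjusted p = 2.1e-04), at 47.7 and 48.1 against 89.1 and 241 FPKM, so that mutant replicate 2 stood apart from the other 3 libraries. The pud family was lower for all 5 tested members, with a median of -1.41 (adjusted p = 3.2e-05) and 123.1 and 107.9 against 33.8 and 61.8 FPKM, and pud-2.1 and pud-2.2 carried the same values in every library. These 4 families kept their direction when each library was left out, and stayed past the threshold with the preset correlation with median-centred or quantile-normalized values. For nspb and pud the signs could not have turned with a library left out, as no member had groups that overlapped. Nor could the medians of abu and idpc, where 8 of 10 and 6 of 7 members were higher without overlap. The kept direction is therefore no evidence for these families. The 4 were picked from the 9: the collagen family col also passed as higher, but turned to lower without dve-1 mutant replicate 2. The families his, mltn, idpp and spe passed as well and kept their direction when each library was left out. The his family holds the 67 histone genes already tested as a list.

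The highly expressed gene F56H9.2, singled out after its values were seen, read 15730 and 17391 FPKM in wild type and 3516 and 2215 FPKM in the mutant (log2 fold change -2.57, limma adjusted p = 0.127). As for oac-59, the difference sat on 1 accession, which read 12412 and 13927 FPKM in wild type and was listed at 0 in both mutant libraries (adjusted p = 0.00313 among single accessions). Its other accession read 3318 and 3464 against 3516 and 2215 FPKM. Among protein-coding genes chosen the same way, Y47D7A.13 read 214 and 284.5 against 824 and 849 FPKM, the protease gene nas-30 read 32.6 and 41.9 against 115 and 130 FPKM, and the transcription factor gene atf-2 read 87.9 and 82.7 against 44.2 and 42.6 FPKM, none past the threshold (limma adjusted p = 0.128, 0.157 and 0.291).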
